A study of Mus musculus with 2 samples.

How the data were processed

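H3K4me3 was measured by ChIP-seq in embryonic mouse forebrain at embryonic day 13.5, with 2 biological replicates of 1 group. The analysis started from 4 peak lists on mm10. Per the labels and file notes, the authors called peaks for each replicate from its own alignment with 1 control, called a pooled list from both alignments with both controls, and made the replicated list from the pooled and the replicate lists. The aligner, the peak caller and the rule by which a pooled peak counted as replicated are not given in the sources used here. For each peak the deposited lists give a score without a fixed range, a fold enrichment (a ratio over control), the −log10 of the p-value and of the q-value, and the summit position. The smallest −log10 p was 2.01 and 2.00 in the deposited replicate lists, and 2.55 to 3.69% of the peaks in each replicate list had a q-value above 0.05, so weak calls were part of the lists. The lists give no read counts, so depth is unknown and no interval from depth is given. Wilson intervals at the 95% level cover the share of peaks or genes only.

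All coordinates are mm10, 1-based, and no peak ran past a chromosome end of the reference. Genes came from GENCODE release M21, and starts in the RefSeq annotation of the same build were used only beside distal peaks. A promoter was the window of 1 kb on either side of any annotated TSS of a gene, and a gene was marked if a replicated peak overlapped it. A domain was a run of peaks joined over gaps of up to 1 kb, and a gene took the widest domain at its promoters. Domains wider than 4 kb were called broad. Distal peaks lay more than 1 kb, and far peaks more than 10 kb, from any TSS. A promoter was CpG-rich if the 1000 bp around any TSS had at least 50% G or C and a CpG observed over expected ratio of at least 0.6. Peaks were shared if at least 50% of their length was covered by the other list. A further 14 replicated peaks on unplaced scaffolds entered the peak counts but no analysis of genes.

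Replicate overlap and promoter share were compared with 100 random placements of the peaks on their chromosomes outside assembly gaps of at least 1000 bp (one-sided permutation). Lists of genes were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 29 lists. Domain widths of lists with at least 5 marked members were compared with 10000 random lists of marked genes of the same size (two-sided permutation), and broad domains by Fisher's exact test, both with the same adjustment over 23 lists. The threshold was an adjusted p of 0.05. Genes are not replicates, so these tests describe the 2 libraries, and spread between replicates is given as SD with n = 2.

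The gene lists covered housekeeping, cell cycle, forebrain progenitor, pallial, subpallial, hem with Cajal-Retzius and choroid plexus, diencephalon, midbrain with hindbrain and spinal cord, eye and pituitary, pan-neuronal, late synaptic, immediate early, astrocyte, oligodendrocyte, microglia and leukocyte, endothelial, erythroid, mesenchyme, muscle and heart, liver and gut, keratinocyte, pluripotency and germ line, trunk and limb, imprinted and Hox genes, and by symbol the olfactory and vomeronasal receptors, clustered protocadherins and replication-dependent histones. Of the listed symbols, Tf, H19, Meg3 and Kcnq1ot1 were not protein-coding genes of that name in the annotation and were left out. Otx2, Pitx1, Lmx1b, Sox17 and Hoxb1 are each on 2 lists. The genes named in the report follow a rule fixed in advance: the 20 protein-coding genes with the broadest domains that also have a promoter peak in both replicates (1 per domain); in each list up to 4 members with the broadest domain and up to 3 without a peak; the 5 genes with the highest fold at the TSS by the lower replicate; the 6 strongest far peaks and the 5 strongest unshared peaks of each replicate; and 25 forebrain and control genes named whatever their values. Examples printed are drawn from these, and Sympk, Nt5c3, Gm43517 and Iscu are named as neighbours sharing a peak or domain.

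The lists, definitions, tests and most alternatives were chosen before the data were examined. The alternatives were an overlap of 1 bp or 80%, only peaks with −log10 q of at least 5 or a fold of at least 4, each replicate list in place of the replicated list, the pooled list, promoter windows of 500 bp or 2 kb, the 5'-most TSS only, no gap or a gap of 3 kb for domains, covered bases instead of span, thresholds of 3 and 5 kb for broad domains, distances of 5 and 10 kb for distal peaks, CpG-rich promoters only, and random lists matched on CpG. Counting only peaks or domains at the promoter of 1 protein-coding gene was added after the data had been seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and overlaps were checked against bedtools 2.31.1 on 2000 intervals. The statistics were tested on simulated data. A shared fraction of 80.0% was recovered as 80.0%, and an r of 0.962 as 0.961. Both of 2 changed lists were called by the test of marked genes, with 1 of 100 unchanged lists called, and a list made 3 times broader was recovered at 2.99 times and called, with 0 of 100 unchanged lists called. The simulated lists held only isolated genes, so these rates do not cover lists whose members share a peak or domain.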

Results

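H3K4me3, histone H3 trimethylated at lysine 4, marks the promoters of active genes and of many genes held ready for transcription. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos of strain B6NCrl at embryonic day 13.5, an age at which the forebrain contains dividing progenitors and young neurons. The data comprised 2 biological replicates of 1 group, each from pooled embryos of both sexes, with no second condition. Comparisons were therefore made between the replicates, between peak lists and between groups of genes. The replicate 1 list held 29626 peaks covering 37.9 Mb, and the replicate 2 list held 30482 peaks covering 38.2 Mb. The list called on both replicates together held 33486 peaks, and the replicated list held 23786 peaks with a median width of 1466 bp. Read counts were not part of the peak lists, so the depth of each library is unknown. Fold enrichment is the value the authors gave each peak, and it was used to describe and rank peaks within a list.

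The first comparison was between the replicates. Promoters of 14361 protein-coding genes carried a peak in both replicate lists, against 86 genes with a peak in replicate 1 only and 127 in replicate 2 only. Of the replicate 1 peaks, 79.9% (95% Wilson interval 79.5 to 80.4%, 23678 of 29626) were covered over at least 50% of their length by replicate 2 peaks. In the other direction the share was 77.9% (77.4 to 78.3%, 23733 of 30482). Random placements of the same peaks on their chromosomes gave means of 1.5% in both directions, and none of 100 placements reached the measured shares (one-sided permutation p = 0.0099 for each direction, the smallest that 100 placements can give). The shared peaks were the strong ones. When the peaks of each list were split into 10 equal bins of fold enrichment, 31.7% of replicate 1 peaks and 28.9% of replicate 2 peaks were shared in the lowest bin, 99.2% and 97.5% in bin 5, and 100% from bin 7 upwards. Both replicates had a peak at 22622 of the replicated peaks (95.1%). Across those peaks log2 fold enrichment gave a Pearson r of 0.960 and a Spearman rho of 0.941, which describe peaks within 2 libraries, since peaks are not independent replicates. The median log2 ratio of replicate 1 over replicate 2 was −0.26, with an SD across peaks of 0.42, so values ran 1.2-fold higher in replicate 2. The lists were not normalised to each other, and fold values are therefore given per replicate.

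**Figure D1:**
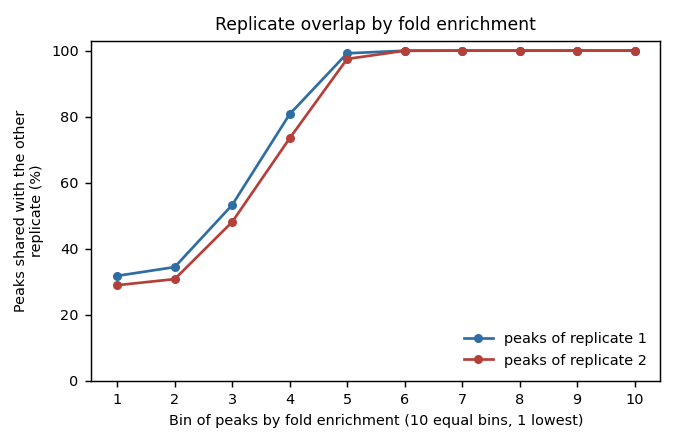
Percentage of each replicate's peaks (y axis) that the other replicate's peaks cover over at least 50% of their length, in 10 equal bins of peaks ranked on fold enrichment within the list (x axis, lowest to highest). The lines rise from 31.7% for replicate 1 and 28.9% for replicate 2 in the lowest bin to 100% from bin 7 upwards.

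Peaks found in a single replicate were weak and lay mostly away from promoters. Replicate 1 had 4611 peaks (15.6% of its list) that touched no replicate 2 peak, with a median fold of 2.84 and a median width of 226 bp, and 24.6% of them lay at a promoter. Replicate 2 had 5296 such peaks (17.4%), with a median fold of 3.06, a median width of 216 bp and 27.0% at a promoter. When both lists were restricted to −log10 q of at least 5, such peaks numbered 898 and 1527, and with a fold of at least 4 they numbered 933 and 1584. Peaks that touched the other replicate's peaks had median folds of 16.1 and 19.6, and 68.3% and 68.0% of them were at promoters. The strongest replicate 1 peak without a partner had a fold of 6.39 and lay between genes, 7.94 kb from the nearest start of Miat, a long noncoding RNA of the nervous system (mm10, chromosome 5, 112237330 to 112237952). The next, with a fold of 6.08, lay 3.62 kb from the imprinted noncoding gene H19 (chromosome 7, 142581766 to 142582078). The others of the first 5 lay at or near Gm38102, Gm12631 and Alkbh5. In replicate 2 the strongest was 24.8 kb from Ocrl on the X chromosome, with a fold of 6.94. The others, with folds of 6.70 to 6.45, lay at the promoter of Tuft1 and near Rpl10a-ps3, Gm22918 and Dab1. With 1 library on each side these differences have no test.

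The replication filter of the authors kept 23786 of the 33486 pooled peaks (71%), and each kept peak stood in the pooled list with the same coordinates. A promoter peak was present at 66.7% of protein-coding genes in the pooled list and at 65.7% in the replicated list. The change was larger for Hox genes, from 82.1 to 53.8%, and for clustered protocadherins, from 59.6 to 43.9%. Both replicates covered 21308 replicated peaks (89.6%) over at least 50% of their length. The 9700 pooled peaks that were dropped had a median width of 225 bp and a median fold of 2.54, against 1466 bp and 23.2 for the kept peaks. When coverage of 50% of either the pooled peak or the replicate peak counted as a match, 22583 pooled peaks were matched in both replicates and all were kept. The other 1203 kept peaks had a median width of 365 bp and a median fold of 3.11.

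The next comparison asked where the mark lies and which genes carry it. Of the 23772 replicated peaks on placed chromosomes, 16407 (69.0%) overlapped a promoter, taken as 1 kb on either side of an annotated transcription start site (TSS). The replicate lists gave 61.2% ± 0.431 (SD, n = 2), and random placements of the replicated peaks gave 10.8%, a 6.38-fold difference (one-sided permutation p = 0.0099, the smallest possible). Exons outside promoters held 5.32% of peaks, introns 12.2% and intergenic sequence 13.5%. A promoter peak was present at 14411 of 21938 protein-coding genes (65.7%, Wilson interval 65.1 to 66.3%), with 65.9% ± 0.132 in the replicate lists (SD, n = 2). The highest enrichment by the lower of the replicates was at Arid1a, Set, Hnrnpr, Sart3 and Iscu. Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, had a fold of 63.7 in replicate 1 and 70.2 in replicate 2. Set, a histone chaperone, had folds of 62.5 and 69.2, and the splicing-related genes Hnrnpr and Sart3 had 62.2 and 68.7, and 62.5 and 68.4. Sart3 shares its peak with Iscu, a gene of iron-sulfur cluster assembly that starts on the opposite strand.

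CpG-rich promoters were nearly all marked. A peak was present at 11122 of 11242 genes with a CpG-rich promoter (98.9%) and at 3289 of 10696 other genes (30.7%), an odds ratio of 209. When peaks were counted at the 5'-most TSS of each gene only, while CpG-rich was still judged over any TSS, the odds ratio was 43.8. The association with CpG content at the 5'-most TSS itself was not measured. The two-sided Fisher's exact p was too small to be represented as a number. The replicate lists gave 99.0% in both cases for CpG-rich promoters, and 31% in both cases for the others. Domains, peaks joined over gaps of up to 1 kb, had a median width of 2.54 kb at CpG-rich and 1.52 kb at other marked promoters. Among noncoding genes the share varied with the type, and no test against protein-coding genes was run. A peak was found at 887 of 5854 long intergenic noncoding RNA genes (15.2%), and at 9.48% of those more than 2 kb from any protein-coding TSS. Bidirectional promoter noncoding RNAs, which start beside a protein-coding gene, had a peak in 178 of 190 cases (93.7%), antisense RNAs in 35.5%, or 8.95% of those more than 2 kb from a protein-coding TSS, and processed pseudogenes in 1.86%.

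Progenitor regulators and genes of the pallial and subpallial lineages of the forebrain all carried the mark, and genes of blood, liver, skin, germ cells and sensory receptors mostly did not. In the lists fixed beforehand, all 24 forebrain progenitor regulators, all 21 genes of the pallial glutamatergic lineage and all 20 of the subpallial GABAergic lineage had a promoter peak in both replicates. These lists include Foxg1 and Pax6, transcription factors of telencephalic progenitors, Neurog2, Eomes and Tbr1, which act in turn in cortical excitatory neurons, and Dlx1, Dlx2, Dlx5 and Gad1 of inhibitory neurons. All 20 pan-neuronal genes such as Tubb3, all 20 late synaptic and ion channel genes, all 20 housekeeping genes, all 20 cell cycle genes and all 16 immediate early genes were marked too. Against 65.7% of the other protein-coding genes, adjusted p in two-sided Fisher's exact tests was 0.000243 for progenitor regulators, 0.00105 for the pallial list and 0.00437 for immediate early genes. It was 0.00112 in the exact tests of the subpallial, pan-neuronal, late synaptic, housekeeping and cell cycle lists. Regulators of the diencephalon, which is part of the forebrain, of more caudal regions of the nervous system and of trunk and limb were marked more often as well, with 17 of 18 genes of the diencephalon and hypothalamus, 18 of 20 of the midbrain, hindbrain and spinal cord and 23 of 25 trunk and limb developmental regulators. For these the exact tests gave adjusted p of 0.0160, 0.0276 and 0.00841. Genes of these lists without a replicated peak were Pomc, Phox2b, Hoxb1, Tbx4 and Hnf1b. Imprinted genes (16 of 17, all but Ndn; adjusted exact p = 0.0160) and replication-dependent histone genes (60 of 67; adjusted exact p = 7.48e-05) were also marked more often than other genes.

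The lists of leukocytes, red blood cells, muscle, liver and gut, skin, germ cells and sensory receptors were marked less often than other genes. None of 16 microglia and leukocyte genes had a peak (adjusted exact p = 3.53e-07), among them Cx3cr1, Csf1r and P2ry12. Of the erythroid genes 4 of 15 were marked (adjusted exact p = 0.00757), namely Tal1, Epor, Klf1 and Gypa, and Gata1 and the globin genes Hba-a1 and Hba-a2 had none. Of muscle and heart genes 6 of 16 were marked (adjusted exact p = 0.0408), including Myod1 with a 2.31 kb domain but not Myf5, Myog or Actc1. The replicate 2 list alone marked 8 of 16 and did not pass the test. Of liver and gut genes 4 of 16 were marked (adjusted exact p = 0.00226), without Alb, Afp or Apoa1, and the peak at Foxa3 also covers the promoter of Sympk. Of keratinocyte genes 5 of 14 were marked (adjusted exact p = 0.0332), without Krt5, Krt14 or Krt15. Of pluripotency and germ line genes 2 of 17 were marked, Esrrb and Dazl (adjusted exact p = 4.84e-05), and Pou5f1, Nanog and Zfp42 had no peak. Olfactory receptors had a peak in 3 of 1135 cases, with a p too small to be represented, and vomeronasal receptors in 1 of 331, Vmn1r4 (adjusted exact p = 1.25e-152), whose peak also covers the promoter of Nt5c3.

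The test was not passed by the lists of the cortical hem, Cajal-Retzius cells and choroid plexus (16 of 18, all but Ttr and Kcne2; adjusted exact p = 0.0569), eye and pituitary (9 of 18), astrocytes (9 of 12, without Gfap, Aqp4 and S100b) and oligodendrocytes (6 of 12, without Plp1, Mog and Mag). It was not passed either by endothelial cells and pericytes (10 of 16, without Pecam1, Cdh5 and Tie1) or by mesenchyme and meninges (13 of 17, without Col3a1, Lum and Tcf21). Unmarked genes of the eye list included Crx, Rho and Opn1sw. In all, 13 of 29 lists were marked more often than other genes, 9 less often and 7 neither, and the 22 lists that passed lay on the same side in both replicate lists. When only genes with CpG-rich promoters were compared, of which 98.9% are marked, none of the 13 lists passed as marked more often. At that share no list of these sizes could pass upwards, even with all members marked. What CpG content contributes to these calls is therefore left open. Histone genes (87.8%) passed as marked less often than the rest (99.0%). Most of the unmarked histone promoters have sequence repeated elsewhere in the genome, where reads may not be placed uniquely. In the CpG-rich comparison the muscle and liver lists had only 4 and 3 members, all marked, and lost their calls. The protocadherins, with 4 of 5 marked, lost theirs too. The unmarked muscle and liver genes all lacked a CpG-rich promoter, so these calls cannot be separated from promoter CpG content. The microglia, erythroid, keratinocyte, olfactory receptor and vomeronasal receptor lists had at most 1 CpG-rich member each and were not tested there. Their calls can therefore not be separated from promoter CpG content. When a peak counted only if it overlapped the promoter window of no other protein-coding gene, the housekeeping list (75%) no longer passed the test and histone genes (37.3%) stood below other genes (53.2%). The imprinted list lost its call with that rule (52.9% against 53.2%), the protocadherin, erythroid, muscle and keratinocyte lists did not pass either, whereas the hem list then did. With the 5'-most TSS only, the hem list passed and the imprinted, midbrain and trunk lists did not. A fold of at least 4 ended the calls of the diencephalon, midbrain and keratinocyte lists, and a 2 kb window or the pooled list those of the muscle and keratinocyte lists.

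**Figure D2:**
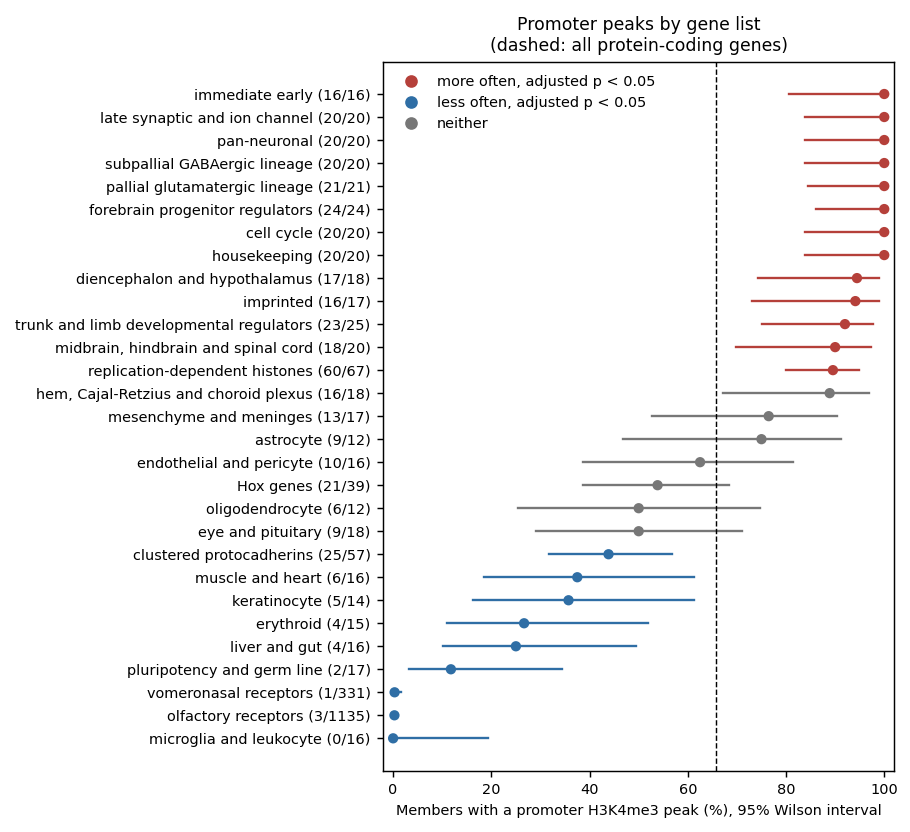
Percentage of the members of each fixed gene list with a promoter H3K4me3 peak in the replicated list (x axis), with 95% Wilson intervals as lines, marked and total members in parentheses and colour by Fisher's exact test. The progenitor, pallial and subpallial lists lie at 100%, above the dashed line of 65.7% for all protein-coding genes, and the microglia, olfactory and vomeronasal lists lie near 0.

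Clustered gene families were marked in part. Of 39 Hox genes, which pattern the body behind the forebrain, 21 had a peak (53.8%, adjusted exact p = 0.157). The share was 5 of 11 in the Hoxa cluster, 3 of 10 in Hoxb, 5 of 9 in Hoxc and 8 of 9 in Hoxd. Hoxa9, Hoxa2, Hoxa3 and Hoxa6 were among those without a replicated peak, and the widest domain in the replicated list, at Hoxc6, was 1.91 kb. In the replicate 1 and 2 lists the Hoxd11 domain (2.30 and 1.31 kb) was wider than that of Hoxc6 (1.57 and 0.857 kb). The Hox result depended on the list and threshold, since the pooled list marked 82.1% of the genes and peaks with a fold of at least 4 marked 41.0%, fewer than other genes. Among genes with CpG-rich promoters 51.7% of Hox genes were marked against 99.1% of the rest, and this difference passed the test. Clustered protocadherins, cell-surface molecules that give neurons individual identities, were marked in 25 of 57 cases (adjusted exact p = 0.00226), by cluster 3 of 14 Pcdha, 3 of 22 Pcdhb and 19 of 21 Pcdhg genes. With the pooled list 59.6% of them were marked and the difference did not pass the test.

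The 20 widest domains at protein-coding genes lay mostly at transcription factors of the forebrain. The widest in the replicated list, 35.4 kb, was at Pou3f3, a POU-domain factor of cortical neurons (mm10, chromosome 1, 42679228 to 42714666), and measured 31.4 ± 0.0962 kb in the replicates (SD, n = 2). The Dlx5 and Dlx6 domain was 32.8 kb wide (chromosome 6, 6850018 to 6882826; 31.4 ± 2.41 kb) and wider than that of Pou3f3 in the replicate 1 list (33.1 against 31.4 kb), and that of Dlx1 and Dlx2, the other paired Dlx locus, was 24.2 kb (chromosome 2, 71523284 to 71547464; 23.8 ± 0.250 kb). Foxg1 lay in a domain of 29.8 kb (chromosome 12, 49372928 to 49402712; 30.1 ± 0.716 kb), which also covers the promoter of the gene model Gm43517. Pax6 had 24.1 kb (chromosome 2, 105666566 to 105690615), with a larger spread between replicates, 20.8 ± 4.46 kb. The others among the 20 widest at protein-coding genes, 1 gene per domain, were Nr2f2 (27.0 kb), Meis2 (24.9 kb), Lhx2 (23.9 kb), Zic1 (23.5 kb), Nfib (22.3 kb), Sox2 (21 kb), Mn1 (20.5 kb), Sox1 (20.3 kb), the X-linked Arx (18.2 kb), Nr2f1 (18.1 kb), Emx2 (16.6 kb), Six3 (16.5 kb), Otx1 (16.4 kb), Lhx5 (16.2 kb) and Bahcc1 (15.9 kb). Replicate widths also differed at other genes, for example at Zic1 with 15.7 kb in replicate 1 and 23.4 kb in replicate 2, and Nr2f1 with 24.7 and 18.9 kb.

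Across the 14411 marked protein-coding genes the median domain was 2.33 kb (quartiles 1.70 and 3.18 kb), and the SD between replicates had a median of 0.122 kb. The progenitor, subpallial and pallial lists were several times broader. Progenitor regulators had a median of 13.6 kb, with 12.9 ± 0.736 kb in the replicates (SD, n = 2), the subpallial list 11 kb (10.5 ± 0.363 kb) and the pallial list 6.79 kb (6.72 ± 0.605 kb). Domains at named members were 13.7 kb at Tbr1, 13.5 kb at Nkx2-1, 10.9 kb at Gad1, 9.68 kb at Emx1, 6.78 kb at Ascl1, 6.25 kb at Eomes, 6.11 kb at Neurod6, 4.55 kb at Neurog2 and 3.50 kb at Gsx2. Pan-neuronal genes, with Tubb3 at 8.31 kb, and immediate early genes, with Jund at 6.62 kb, both had a median of 4.24 kb, and histone genes had 3.91 kb. For each of these 6 lists none of 10000 random lists of marked genes was as broad (two-sided permutation, adjusted p = 0.000575, from the smallest p possible, 0.0002). Smaller increases passed the permutation test for the diencephalon and hypothalamus (3.73 kb, adjusted p = 0.00138), hem, Cajal-Retzius and choroid plexus (3.72 kb, 0.00383), imprinted (3.64 kb, 0.00209), housekeeping (3.45 kb, 0.00566) and cell cycle lists (3.24 kb, 0.0152). The diencephalon result rested on replicate 2, since the replicate 1 list alone gave 2.82 kb and did not pass. With no joining of peaks over gaps the diencephalon (2.43 kb), hem (2.68 kb) and histone lists (2.04 kb) no longer passed, and the histone median then lay below that of random lists. The diencephalon list did not pass either with a fold of at least 4, the hem list with stricter peaks of either kind, the imprinted and histone lists with domains of 1 protein-coding gene, where the histone median (2.10 kb) again lay below that of random lists, and the cell cycle list with pooled peaks.

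Narrow domains were found at Hox genes, clustered protocadherins and genes of muscle, skin, eye and oligodendrocytes. Hox genes had a median of 1.03 kb and clustered protocadherins 0.964 kb (permutation, adjusted p = 0.000575 for both). Muscle and heart genes had 0.883 kb, oligodendrocyte genes 1.16 kb, keratinocyte genes 1.23 kb and eye and pituitary genes 1.33 kb (permutation, adjusted p = 0.00102, 0.00887, 0.0333 and 0.0117). These 4 lists had 6, 6, 5 and 9 marked members. Median folds in replicates 1 and 2 were low at Hox (3.79, 4.70), protocadherin (5.21, 5.90), muscle (6.26, 4.90) and eye genes (5.21, 6.70). At oligodendrocyte (13.2, 16.5) and keratinocyte genes (18.6, 27.0) they were higher, against 37.8 and 47.4 at all CpG-rich marked promoters. Whether narrow width goes with weak signal was not tested for these lists. Each of the 11 broader and 6 narrower lists lay on the same side of the median of all marked genes in both replicates. The 6 lists that did not pass were late synaptic and ion channel genes (3.02 kb, adjusted permutation p = 0.0537), astrocytes (3.36 kb, 0.0688), midbrain, hindbrain and spinal cord (2.30 kb), with En1 at 2.05 kb, endothelial cells and pericytes (2.21 kb), mesenchyme and meninges (2.04 kb) and trunk and limb developmental regulators (2.73 kb). In the replicate 1 list alone the mesenchyme median was 1.51 kb and passed the test as narrower. With a 3 kb gap the trunk and limb (3.42 kb) and midbrain (3.97 kb) lists passed as broader. The late synaptic list passed as broader under 7 alternatives and the astrocyte list under 2, in both cases including random lists matched on promoter CpG. With that matching the keratinocyte and eye lists no longer passed as narrower, and with a 3 kb gap or with domains of 1 protein-coding gene the keratinocyte and oligodendrocyte lists did not.

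**Figure D3:**
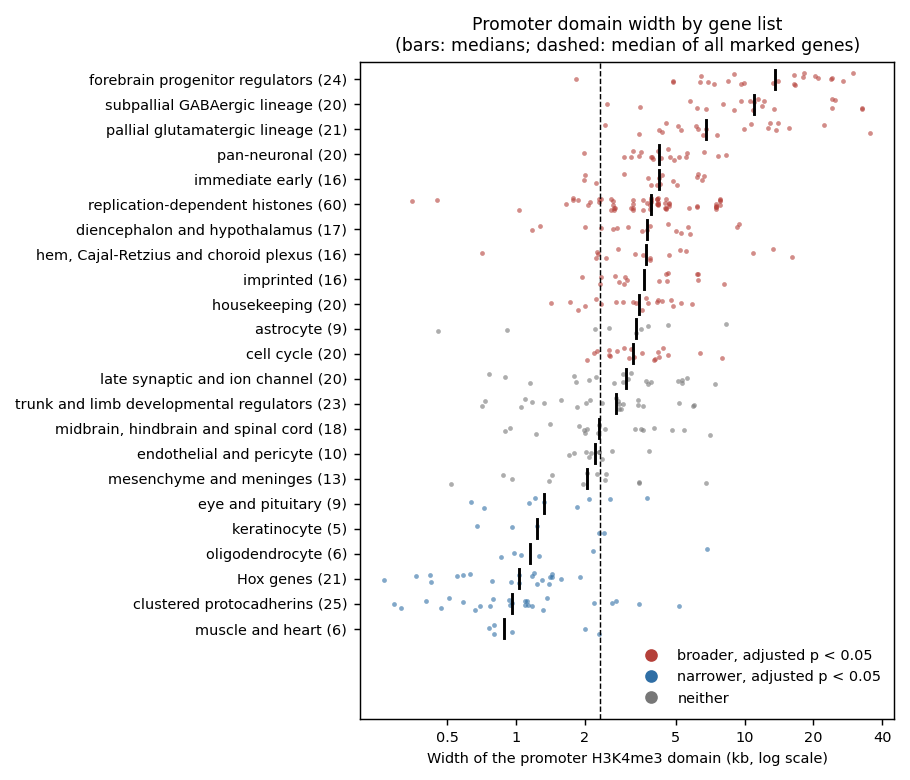
Width of the promoter H3K4me3 domain in kb (x axis, log scale) for each marked member (points) of the lists with at least 5 marked members, with list medians as bars and the median of all marked genes, 2.33 kb, as a dashed line. The progenitor, subpallial and pallial lists have the highest medians, 13.6, 11 and 6.79 kb.

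Domains wider than 4 kb numbered 1541 and covered the promoters of 1854 genes, 12.9% of those marked. Of these domains 77.5% (1195) were wider than 4 kb in both replicates, 84.0% in replicate 1 and 87.0% in replicate 2, and 81 were wider than 10 kb. They held 23 of 24 progenitor regulators (95.8%, adjusted two-sided exact p = 1.41e-18), 19 of 21 pallial genes (90.5%, exact p = 2.06e-14) and 18 of 20 subpallial genes (90.0%, exact p = 9.76e-14). Immediate early genes were in such domains in 62.5% of cases, pan-neuronal genes in 55%, imprinted genes in 8 of 16 cases, with Nnat at 8.11 kb and Mest at 6.22 kb, and histone genes in 46.7%. The adjusted exact p was 2.14e-05, 3.28e-05, 0.00120 and 8.87e-10. Lower shares passed the exact test for the diencephalon (41.2%, adjusted p = 0.00994), the hem list (37.5%, 0.0239) and the housekeeping and cell cycle lists (35.0%, 0.0224 for both). In the replicate 2 list alone the housekeeping and cell cycle lists stood at 6 of 20 genes each and did not pass, nor did they with a threshold of 5 kb. With no gap joined the cell cycle, diencephalon, hem and histone lists did not pass, and stricter peaks also ended the call of the hem list and, with a fold of at least 4, of the cell cycle list. Genes of a list can share a domain, as Dlx5 and Dlx6 do, so the members are not independent of each other.

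**Figure D4:**
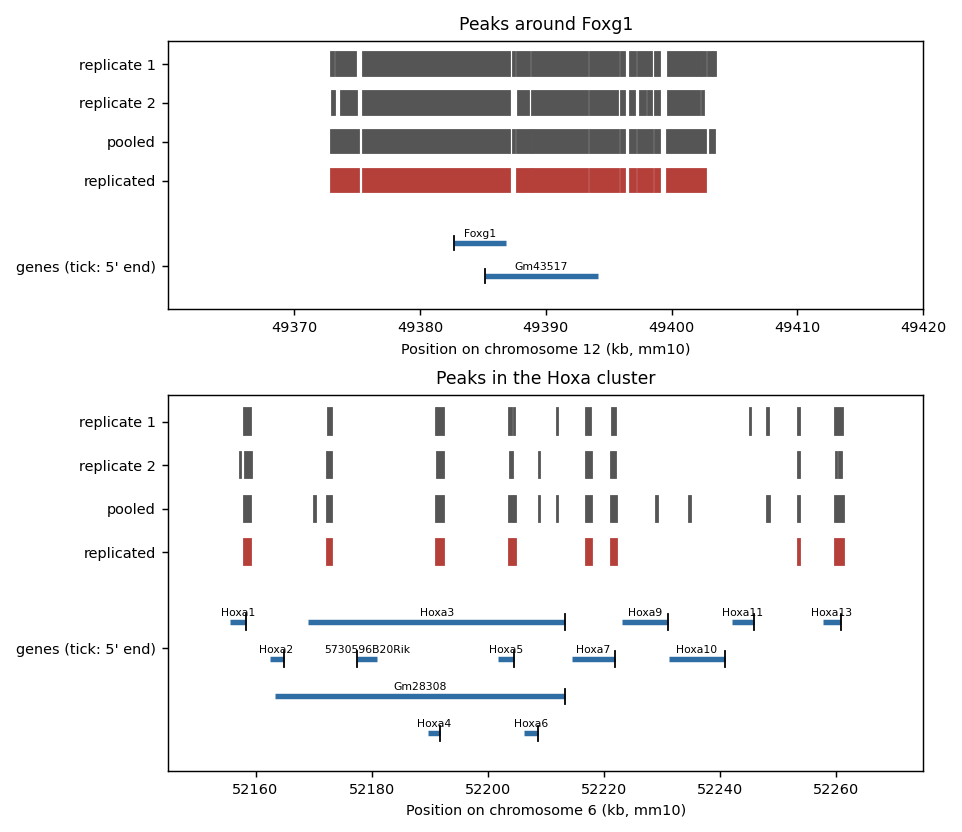
Peaks of the 4 lists (rows) and annotated genes with their 5' ends (ticks) by position in kb on mm10, around Foxg1 on chromosome 12 and in the Hoxa cluster on chromosome 6. Peaks run almost without a break over 29.8 kb at Foxg1, while 5 of 11 Hoxa genes have short replicated peaks at their promoters.

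The last comparison was between promoter peaks and peaks away from annotated starts. A distance of more than 1 kb from any TSS was found for 7365 replicated peaks (31%), against 38.8% ± 0.431 of the replicate lists (SD, n = 2). These distal peaks had a median width of 610 bp against 1969 bp at promoters. Their median fold was 4.50 against 30.2 in replicate 1 and 4.84 against 37.7 in replicate 2. A CpG-rich summit was found in 10.9% of distal and 64.9% of promoter peaks, and 10.2% of distal peaks lay within 1 kb of a TSS in the RefSeq annotation. More than 10 kb from any TSS lay 2903 peaks (12.2%; replicates 12.4% ± 0.20). The strongest of them, with folds of 53.5 in replicate 1 and 61.8 in replicate 2, was 5380 bp wide and lay in an intron of the noncoding gene Lncppara (chromosome 15, 85669614 to 85674993). A peak in an intron of Ldb3, a muscle cytoskeletal gene, had folds of 43.9 and 52.8 (chromosome 14, 34548295 to 34549855). Intergenic peaks followed 32.4 kb from Pum2 (chromosome 12, 8640103 to 8641773; folds 43.3 and 50.8) and 23.2 kb from Wnt10a (chromosome 1, 74816584 to 74817784; folds 39.8 and 43.9). The remaining pair, on chromosome 9 (67631680 to 67634754) and chromosome 18 (23309653 to 23311351), lay within 1 kb of RefSeq starts of Tln2 and Dtna.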

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

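In this part, the 3 comparisons with other lists of developmental regulators and all tests of the replication filter were chosen after the result was seen. The design has 1 group, so no biological explanation from a comparison of groups was tested here.

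Signal was present outside the chromosomes used for the comparisons. The replicated list held 14 peaks on 6 scaffolds not placed on a chromosome, with a median fold of 9.95 and a highest fold of 36.7.

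Domains at the progenitor, pallial and subpallial lists together, 65 genes of 3 lists, had a median of 10.6 kb against 2.33 kb for random lists, 4.54-fold. Joining of neighbouring promoters was argued against, since 60 genes in domains with 1 protein-coding gene and no joining over gaps still had 6.63 kb against 2.12 kb (3.13-fold). The CpG count within 5 kb of the TSS did not account for all of the width, since random lists matched on its deciles left 2.90-fold (3.65 kb). With a median of 10.6 kb, many domains reach beyond that window, and deciles do not separate genes with the highest counts. A larger part for CpG content along the domains was therefore not excluded. Enrichment at the promoter was argued against as the whole cause by lists matched on fold (4.71-fold). Breadth of the same size was not found at 61 marked regulators of the midbrain and hindbrain, trunk and limb, and Hox lists (1.58 kb), nor at 57 of the diencephalon, midbrain and trunk lists without Hox genes (2.78 kb, or 4.58 against 12.8 kb with a 3 kb gap; two-sided permutation p = 1e-05 each, the smallest that 100000 permutations can give). The diencephalon list was itself broader than random lists (3.73 kb) and is part of the forebrain, so these tests argue against equal breadth at all regulators and not against smaller breadth at some, and the share of cells that carry the mark was not tested.

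A peak was missing at 120 genes with CpG-rich promoters, a type of promoter that was marked in 98.9% of cases. Among the 102 outside the Hox and germ line lists, 53.9% had at least 50% of their promoter's 32-base words repeated elsewhere in the genome, against 0.4% of 500 marked promoters, which is consistent with reads that cannot be placed uniquely (examples are Entpd4, Loxl2 and Hist1h2ao, named after their values were seen). None of the 18 Hox and germ line genes had such promoters (0%), so repeated sequence was argued against for them. Of the 14 Hox genes, 78.6% (11) had a promoter peak in the pooled list or in a replicate list, so the replication filter may account for most of them. Such calls can be weak, since the pooled peak at Hoxa6 had a fold of 2.68 and all dropped pooled peaks a median of 2.54. A peak in those lists was present at 1 of 4 germ line genes (25%) and 10.8% of the other 102 genes. The pluripotency and germ line list held 17 genes, so the 102 may include other germ line genes, which were not counted. For the remaining genes the cause stays open.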

How the results depend on the processing

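Counting only peaks or domains of 1 protein-coding gene was the alternative chosen after the data were seen. Across 1782 alternative values, 1264 stayed on their side of the threshold or within the replicate spread, 54 no longer passed the test, 16 newly passed it, 23 changed direction and 425 moved by more than the replicate spread, of which 394 were widths of single genes. No paired analysis was possible because there is 1 group. Depth is not known, so its effect on weak peaks cannot be separated from the thresholds. Replicate overlap, promoter share and the association with CpG-rich promoters kept their direction and passed their tests under all alternatives run for them. The odds ratio of 209 moved to 43.8 when peaks, but not CpG content, were taken at the 5'-most TSS only. The counts of broader and narrower lists stayed within 1.5 times. Where no reason is given, the cause was not tested.

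Stricter lists keep fewer weak peaks by construction. With −log10 q of at least 5, 97.6% of pooled peaks were retained, 93.9% of replicated peaks were covered in both replicates, 65.5% of genes had a peak, 27.8% of peaks were distal, and 898 and 1527 peaks were specific to replicates 1 and 2. With a fold of at least 4 these values were 99.9%, 98.0%, 64.9%, 22.4%, 933 and 1584, and r was 0.959. An overlap of 1 bp gave 95.1% covered in both, and averaging the overlapping peaks gave an r of 0.938. The pooled list gave 66.7% of genes with a peak, 43.5% distal peaks, 82.1% of Hox genes marked and a width of 2.99 kb for the midbrain, hindbrain and spinal cord list. A 500 bp window gave 65.2% of genes, a 2 kb window 66.4% and the 5'-most TSS 62.2%, with 62.5% of the endothelial list against 62.2% of other genes. Distances of 5 and 10 kb left 17.6% and 12.2% of peaks distal. Thresholds of 3 and 5 kb gave 3512 and 778 broad domains.

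Leaving out a replicate, so that the other's list was used alone, gave 65.9 to 66.0% of genes with a peak, 38.5 to 39.1% distal peaks, 62.5 to 68.8% of endothelial genes marked and 2.13 to 2.33 kb for the midbrain list.

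Among CpG-rich promoters only, 24 lists had enough members to be tested, and 0 were marked more and 3 less often. No list of these sizes could pass as marked more often there, even with all members marked. The eye, oligodendrocyte, endothelial, muscle and liver lists then stood at 100% against 98.9% of other genes, and trunk and limb at 95.7%, where few genes are left to differ. Histones, at 87.8% against 99.0%, went from marked more often to marked less often, and the latter passed the test. Among the unmarked CpG-rich histone genes, Hist1h2ao, Hist1h2ap, Hist1h2bq and Hist1h2br had 100% of their promoter's 32-base words repeated, so reads without a unique place may contribute to that call. The others, Hist1h2aa and Hist1h2ba, had 4.95% and 17.6%. These genes were named after their values were seen. With peaks of 1 gene only, the endothelial list stood at 62.5% and imprinted genes at 52.9% against 53.2%, and histones at 37.3%.

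With no gap joined, 7 lists were enriched among broad domains, and median widths were 1.92 kb for trunk and limb and 2.04 kb for histones. With a gap of 3 kb they were 3.97 kb for the midbrain list, which then passed as broader, and 2.44 kb for mesenchyme. Matching on CpG put the endothelial list (2.21 kb) above its random lists, as did domains of 1 gene (2.21 kb), which also moved the midbrain list (2.30 kb) above and histones (2.10 kb) below theirs. Of the 132 named domains, 44 changed by more than 1.5 times with no gap joined, 20 with a 3 kb gap and at most 12 under each other setting.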

Other observations

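All genes in this part were named after their values were seen, except the 5 X-linked genes transcribed from both copies. All tests of this part were chosen before their results were seen. A first run of the third test used the 4 of these genes with CpG-rich promoters, and it gave the same percentile as all 5.

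Some noncoding genes had broad domains as well. Of 673 promoter domains of long noncoding RNAs that overlapped no protein-coding promoter, the median width was 1.19 kb and 41 were wider than 4 kb. The widest was 30 kb at C130071C03Rik on chromosome 13 (83712849 to 83742897), with 29.8 ± 0.132 kb in the replicates (SD, n = 2). AW047730 had 26.5 kb (27.1 ± 2.73 kb), Mir9-3hg 25 kb (24.5 ± 0.985 kb), Mir124-2hg 12.1 kb (12.9 ± 1.2 kb) and Mir124a-1hg 9.25 kb (9.32 ± 0.193 kb). By their names, Mir9-3hg, Mir124-2hg and Mir124a-1hg are host genes of miR-9 and miR-124, microRNAs of neural progenitors and neurons. Whether C130071C03Rik and AW047730 host microRNAs as well was not examined. Malat1, an abundant nuclear RNA, had 9.64 kb.

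On the Y chromosome 4 of 183 protein-coding genes had a promoter peak, Kdm5d, Uty, Ddx3y and Eif2s3y, which are broadly transcribed relatives of X-linked genes. On the X chromosome 487 of 948 genes were marked (51.4%), with a median fold of 28.4, below the autosomes, which ranged from 43.3 to 47.7. Fewer X-linked genes had a CpG-rich promoter (29.4%) than genes of any autosome (38.2 to 68.6%). Of the CpG-rich X-linked genes 97.8% were marked, within the autosomal range of 95.3 to 100%.

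Among CpG-rich marked promoters, 273 X-linked genes had a median fold of 25.1 in replicate 1 and 30.8 in replicate 2, against 38.1 and 47.8 at 10849 autosomal genes. CpG content was argued against, since matched autosomal sets had 47.2 against 31.2 in the replicated list (ratio 0.662), and so was repeated promoter sequence, since promoters with under 5% repeated words gave a ratio of 0.624 (31.3 against 50.2). A candidate explanation is that 1 X copy is active per cell, in which case genes transcribed from both copies in females would stand above other X-linked genes. Kdm6a, Kdm5c, Ddx3x, Eif2s3x and Pbdc1 had a median of 50.4 in the replicated list. This was percentile 100 of random sets of the same size from the 273 X-linked genes, although Pbdc1, whose promoter is not CpG-rich, had 27.0 and 26.3 in the replicates. The sets were not matched on expression, which was not measured, so the test cannot separate 2 active copies from broad or strong transcription of these genes. A single active copy remains a hypothesis from 5 genes in pooled embryos of both sexes.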
